A study of Homo sapiens with 18 samples.

How the data were processed

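Total RNA of U251 cells was extracted with Trizol, labelled as biotinylated cRNA and hybridized to Affymetrix HG-U133 Plus 2.0 arrays. Cells in RPMI medium with 5% serum were exposed to DMSO or enzastaurin for 4, 10 or 18 h, with 3 arrays in each of the 6 groups. The deposited table gives 1 signal intensity on a linear scale for each of 54613 probe sets and 18 arrays, made by the authors with GCOS 1.2. Its values run from 0.1 to 63584.9, and the 2% trimmed mean lies between 498.2 and 498.5 in every array, so each array had been scaled to a common level. No detection calls and no scan files were used. Array medians lay between 99.2 and 125.9.

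Gene symbols came from the platform annotation, matched by gene identifier to the RefSeq names of the human assembly GRCh38.p14. Of the probe sets, 41091 had 1 symbol, 1801 had several and 11721 had none, and only those with 1 symbol entered the gene analysis. For each of the 19775 genes the probe set with the highest mean over the 18 arrays was kept, and genes under the median mean level of all probe sets (an intensity near 102) were left out, which left 12376 genes. Values were analysed as log2 of the intensity plus 16, with no further normalization.

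A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend on mean level. The contrasts were enzastaurin minus DMSO at 4, 10 and 18 h, their average, the differences of these effects between times, and DMSO at 18 h minus 4 h. Benjamini-Hochberg adjusted p values under 0.05 were called, over all genes of a contrast. The median standard error of a log2 change was 0.134 at each time, 0.0773 for the average and 0.189 for differences between times. The same pipeline was tested on simulated data with 50 genes shifted at each size, at 18 h only. There 44% were called at a log2 change of 0.5, 76% at 1, 88% at 1.5 and 98% at 2. Of 156 calls 3 were false. The noise was simulated as independent between genes, and far fewer genes were shifted than the 1981 called in the data at 18 h. These rates need not hold for the data.

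In total 25 gene lists were written from general knowledge before the data were examined, with 575 members of which 467 were tested. They cover drug targets (GSK3 and protein kinase C genes), NF-kB targets, MYC-activated and MYC-repressed targets, glycolysis and glucose uptake, glycogen and gluconeogenesis, hypoxia response, Wnt and beta-catenin targets, G1/S and DNA replication, G2/M and mitosis, integrated stress response, ER chaperones, heat shock proteins, p53 targets, apoptosis regulators, cholesterol synthesis and SREBP targets, FOXO targets, immediate early and ERK feedback genes, interferon-stimulated genes, autophagy and lysosome, TGF-beta and YAP targets, NRF2 targets, aryl hydrocarbon receptor targets, astroglial and glioma markers, and markers of other cell types. Lists were tested with camera at a fixed correlation between genes of 0.01, adjusted over the 75 tests of the 3 times, and over 25 lists for each other contrast. The correlation estimated from the data, and the rotation test fry, were alternatives.

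Genes were named by a rule written before the data were examined. At each time it takes the 8 largest rises and 8 largest falls among called genes with all 3 treated arrays beyond all 3 DMSO arrays and a mean of the brighter group at or above the median level. It adds up to 4 members of each list with the smallest adjusted p, and MYC and the drug target genes in any case. For the average, the differences and DMSO over time it takes the 5 largest changes in each direction. Symbols of uncharacterized loci were not named. Other genes singled out, among them list examples in DMSO cells over time and the gene families in the closing section, were chosen after their values were seen.

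Alternatives changed 1 choice at a time. They were an offset of 1 or 64, no level filter or only the brightest 25% of probe sets by mean level, quantile normalization, array medians subtracted, the mean over the probe sets of a gene, every probe set on its own, array weights, no trend, only the groups compared, replicate numbers as blocks, a 2-fold minimum, and each array left out in turn. Replicate numbers were checked as possible pairs. Arrays with the same number correlated at -0.0814 to 0.0544 after group means were removed, so they were not treated as pairs. Leaving out together the 2 arrays that deviate most from their groups was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.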

Results

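The series is titled as a study of how blocking the kinase GSK3 kills glioma cells, with the transcription factor MYC, NF-kB and glucose as its themes. U251 is an established human glioblastoma cell line. Enzastaurin is a kinase inhibitor developed against protein kinase C beta, and DMSO is its solvent. Cells were exposed to DMSO or to enzastaurin for 4, 10 or 18 h, which gives 6 groups of 3 arrays. The dose of enzastaurin is not stated in the labels. Each of the 18 Affymetrix HG-U133 Plus 2.0 arrays gave 1 scaled intensity for each of 54613 probe sets. Array medians lay between 99.2 and 125.9, and the correlation between arrays of the same group lay between 0.977 and 0.986. The number of arrays per group limits the precision. Changes are log2 differences between group means, each estimated from 3 arrays per group, and p values are adjusted over the 12376 genes tested. The labels do not say that replicates were separate cultures, so p values measure only the spread between these samples, which may be technical.

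After 4 h of enzastaurin, cells held more mRNA of AXIN2, a negative feedback gene of the Wnt pathway, and of DDIT4, a stress-induced inhibitor of mTORC1. AXIN2 intensity was 223 ± 7.77 in DMSO and 1157 ± 32.15 in enzastaurin (SD, n = 3 each), a log2 change of 2.29 (SE 0.13, adjusted p = 1.2e-09). DDIT4 rose by 2.25 (adjusted p = 8.2e-10). INSIG1, which retains the sterol-responsive SREBP factors in the endoplasmic reticulum, rose by 1.26 (adjusted p = 1.6e-09). MYC mRNA (from its only probe set) was 1684 ± 159 in DMSO and 1032 ± 88.85 in enzastaurin, a change of -0.70 (SE 0.11, adjusted p = 0.00081). EFNA1, a ligand of Eph receptors, fell to a log2 change of -2.20 and the kinase gene SGK1 to -1.24, with adjusted p values of 0.0011 and 3.7e-07. HEXIM1, an inhibitor of the elongation kinase P-TEFb, changed by -1.18 and MYLIP, a ubiquitin ligase gene, by -1.13. TAMALIN, which encodes a scaffold protein, changed by -2.40 (adjusted p = 0.0014). DUSP1, a phosphatase that inactivates MAP kinases, changed by -1.14 on its brightest probe set, while its other probe set showed 0.00.

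In total 224 genes changed at 4 h, 69 higher and 155 lower, and 16 of them changed at least 2-fold. The zinc finger genes ZNF703 (0.91) and ZNF503 (0.88) also rose, and both calls were lost when the probe sets of a gene were averaged. Among the 16 genes with the largest rises or falls by the naming rule, PIK3C2B (1.41), CHAC1 (1.16), ACSF3 (1.16), SLC12A1 (-1.53) and ZFP36 (-1.43) had calls that depended on single arrays. PIK3C2B lost its call without any 1 of 5 of the 6 arrays (adjusted p up to 0.0893), ACSF3 and ZFP36 without any 1 of 4 (up to 0.0960 and 0.0910), and CHAC1 and SLC12A1 without any 1 of 3 (up to 0.0839 and 0.162). The 4 h count itself fell to 148 without DMSO replicate 1, 143 without DMSO replicate 3 and 138 without enzastaurin replicate 1. The 4 h balance held with quantile normalization (241 genes, 65 higher and 176 lower) but not with array medians subtracted. Subtracting each array's median put the median 4 h change of all genes at 0.12 and left 79 genes, 54 higher and 25 lower, and the call of MYC was then lost (-0.58, adjusted p = 0.0582).

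Of the lists fixed beforehand, 9 of 25 shifted at 4 h, 4 upward and 5 downward, and 4 of the 9 also did with an estimated correlation. Cholesterol synthesis and SREBP targets rose (24 measured, median 0.17, adjusted p = 1.2e-06, and 0.0052 with an estimated correlation), with 3 members higher and 21 not passing. The 3 were INSIG1, SCD, a fatty acid desaturase (0.60), and MSMO1, a sterol oxidase (0.67), and 5 passed when adjusted over the list alone. ER chaperones rose (19 measured, median 0.13, adjusted p = 3.3e-05), with DNAJB9 (0.70) and the transcription factor XBP1 (0.32) higher, and 4 higher adjusted over the list alone. G2/M and mitosis genes fell (32 measured, median -0.12, adjusted p = 9.5e-08), with KIF20A, a mitotic kinesin (-0.43), and AURKA, a spindle kinase (-0.38), lower and 5 lower adjusted over the list alone. With an estimated correlation the adjusted p was 0.012 for ER chaperones and 0.035 for G2/M and mitosis genes. Immediate early and ERK feedback genes fell (26 measured, median -0.17, adjusted p = 4.8e-06, and 0.035 with an estimated correlation). Here 8 members were lower and none higher, among them DUSP1, JUN (-0.69), KLF4 (-0.77) and JUND (-0.51), against 9 lower and 1 higher adjusted over the list alone.

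The other 5 calls at 4 h were lost with an estimated correlation. Integrated stress response genes rose (25 measured, median 0.12, adjusted p = 3.2e-05, and adjusted p = 0.115 with an estimated correlation). Its 5 higher members included DDIT4, TRIB3, a pseudokinase gene (0.46), and SESN2, a stress-induced mTORC1 inhibitor (0.52), and CEBPB was lower (-0.35), with 8 higher and 1 lower adjusted over the list alone. MYC-activated targets rose (29 measured, median 0.10, adjusted p = 0.0035, and adjusted p = 0.081 with an estimated correlation), with no single member passing either way of adjusting. MYC-repressed targets fell (10 measured, median -0.42, adjusted p = 2.8e-05, and adjusted p = 0.0503 with an estimated correlation). KLF4 and GAS1 (-0.83), a growth arrest gene, were its lower members, and 6 were lower and 1 higher adjusted over the list alone. TGF-beta and YAP targets fell (23 measured, median -0.05, adjusted p = 0.013, and adjusted p = 0.128 with an estimated correlation), with CCN2 (-0.68), TGIF1 (-0.73), CCN1 (-0.51) and LATS2 (-0.39) lower, and 7 lower and 1 higher adjusted over the list alone. FOXO targets fell (21 measured, median -0.15, adjusted p = 0.038, and adjusted p = 0.089 with an estimated correlation). BCL6 (-0.97), IRS2 (-0.53), CITED2 (-0.74) and CCNG2 (-0.85) were its lower members, and 5 were lower and 1 higher adjusted over the list alone. The FOXO call was lost without DMSO replicate 3, enzastaurin replicate 1 or enzastaurin replicate 2, with adjusted p values up to 0.118. Among list members, GAS1, AURKA, SESN2 and LATS2 lost their 4 h calls without any 1 of 2 of the 6 arrays (adjusted p up to 0.115, 0.0862, 0.0585 and 0.0862), and XBP1 and CCNG2 without any 1 of 4 (up to 0.149 and 0.202). Averaging the probe sets of a gene also ended the 4 h calls of DUSP1, KLF4, JUND, SCD, BCL6, CITED2 and TGIF1, and subtracting array medians ended 23 calls of named genes, among them MYC, KIF20A, AURKA, JUN, JUND, CEBPB, XBP1, CCN1, LATS2, IRS2, CITED2, CCNG2, GAS1, ZFP36, SLC12A1, DKK1, IER3, CASP2, SOX2 and PFKFB3.

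After 10 h, AXIN2 was higher at 1641 ± 90.3 against 200 ± 27.4 (SD, n = 3 each, log2 2.95, adjusted p = 1.1e-11). INSIG1 rose from 885 ± 58.3 to 4804 ± 289 (log2 2.42, SE 0.08, adjusted p = 1.9e-14), and LIPG, the endothelial lipase gene, rose by 2.28 (adjusted p = 2.0e-07). The stress genes SESN2 (1.93) and DDIT4 (1.84), the receptor gene TNFRSF19 (1.67) and SYTL2 (1.61), which encodes a vesicle trafficking protein, also rose. LFNG, a glycosyltransferase that modifies Notch receptors, changed by -2.05 (adjusted p = 3.6e-08) and KCTD4 by -1.69 (adjusted p = 6.5e-06). GPRC5A (-1.93), RNF122 (-1.46) and SAMD9 (-1.38) fell as well. MYC was lower, at 916 ± 79.0 against 1554 ± 62.8 (log2 -0.75, SE 0.11, adjusted p = 1.0e-04). In total 1046 genes changed, 466 higher and 580 lower, 74 of them at least 2-fold.

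Integrated stress response genes rose at 10 h, with 20 of 25 members higher and none lower (median 0.59, adjusted p = 9.3e-34, and 5.0e-04 with an estimated correlation), and 23 higher adjusted over the list alone. Examples besides SESN2 and DDIT4 were TRIB3 (1.47) and ASNS, asparagine synthetase (1.02). Cholesterol synthesis and SREBP targets rose, with 16 of 24 members higher and none lower (median 0.47, adjusted p = 3.5e-25), and 18 higher adjusted over the list alone. MSMO1 (1.42), IDI1, an isomerase of the isoprenoid pathway (1.30), and SCD (1.27) were among them. ER chaperones rose, with 8 of 19 higher (median 0.24, adjusted p = 2.1e-10) and 10 higher adjusted over the list alone, including DNAJB9 (1.11), XBP1 (1.03), HERPUD1 (1.01) and HSPA5 (0.50). MYC-activated targets rose although MYC mRNA was lower, with 6 of 29 higher and none lower (median 0.19, adjusted p = 5.2e-07, and 0.0084 with an estimated correlation), and 15 higher adjusted over the list alone. SHMT2, a mitochondrial one-carbon enzyme (0.39), and the ribosome biogenesis gene RRP9 (0.66) were examples. TGF-beta and YAP targets fell, with 7 of 23 lower and 1 higher (median -0.24, adjusted p = 2.1e-04, and 0.038 with an estimated correlation), and 9 lower and 1 higher adjusted over the list alone. CCN2 (-1.32), CCN1 (-1.08), SMAD6 (-1.22) and TGIF1 (-0.67) were lower.

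At 10 h 8 of 25 lists shifted, and the calls of the remaining 3 were lost with an estimated correlation. Wnt and beta-catenin targets shifted upward (adjusted p = 0.018, and adjusted p = 0.23 with an estimated correlation) with a mean of 0.40 but a median of -0.04. Of its 13 measured members 5 were higher, among them AXIN2, TNFRSF19, ZNRF3, a ligase that removes Wnt receptors (1.14), and LEF1, a partner of beta-catenin (0.71). MYC and DKK1, a secreted Wnt inhibitor (-0.96), were lower, and adjusted over the list alone 5 were higher and 3 lower. MYC-repressed targets fell (median -0.32, adjusted p = 0.043, and adjusted p = 0.30 with an estimated correlation), with NDRG1 (-1.05), CDKN1A (-0.68) and CDKN1B (-0.36) lower and GADD45A (0.37) higher. Adjusted over the list alone, 6 were lower and 2 higher. That call was lost without DMSO replicate 1, DMSO replicate 3 or enzastaurin replicate 3 (adjusted p up to 0.149). Interferon-stimulated genes fell (21 measured, median -0.24, adjusted p = 0.030, and adjusted p = 0.26 with an estimated correlation). IFIT3 (-0.96), IFI44 (-0.33) and ISG15 (-0.39) were lower, the same number adjusted over the list alone, and the call was lost without DMSO replicate 2 or enzastaurin replicate 2 (adjusted p up to 0.128).

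Among the most changed genes at 10 h, 4 had calls that depended on single arrays. CYP2B7P (1.59) and HSD17B1 (-1.88) lost theirs without any 1 of 2 of the 6 arrays (adjusted p up to 0.0727 and 0.0908), and DHRS3 (-1.72) and ARHGAP23 (-1.38) without any 1 of 5 (up to 0.180 and 0.185). The count fell to 653 without DMSO replicate 2 and to 685 without DMSO replicate 3, and subtracting array medians left 443 genes. The latter ended 21 calls of named genes, among them ARHGAP23, IER3, CDKN1B, PMAIP1, CASP2, PLK1, TOP2A, IFI44 and ISG15. ISG15 lost its call without any 1 of 5 of the 6 arrays (adjusted p up to 0.130) and IER3 without DMSO replicate 3 (adjusted p = 0.0531). Averaging probe sets ended the 10 h calls of XBP1, IDI1, IFI44, SMAD6 and TOP2A.

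After 18 h, AXIN2 was higher at 3138 ± 199 against 185 ± 45.3 (SD, n = 3 each, log2 4.00, SE 0.13, adjusted p = 5.9e-14). The Wnt feedback gene NKD1 rose by 2.28 (adjusted p = 1.1e-06), TNFRSF19 by 2.21 and the receptor gene GPRC5B by 2.31. FAS, which encodes a death receptor, rose from 228 ± 23.6 to 1094 ± 85.0 (log2 2.19, SE 0.17, adjusted p = 9.4e-09). SYTL2 (2.58), LIPG (2.35) and the histone gene H2BC12 (1.96) were also higher. MYC was lower, at 1184 ± 201 against 2433 ± 82.6 (log2 -1.04, SE 0.11, adjusted p = 6.6e-07). DHRS3, a retinal reductase gene, changed by -3.54 (adjusted p = 3.1e-05), the protease-like gene PRSS35 by -2.22 and the growth factor receptor gene PDGFRA by -2.21. UBALD1 (-2.35), ASPG (-1.97), UBALD2 (-1.82) and the tight junction gene CLDN4 (-1.78) fell too. In total 1981 genes changed, 1003 higher and 978 lower, 197 of them at least 2-fold.

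Wnt and beta-catenin targets rose at 18 h, with 7 of 13 members higher and 1 lower (median 1.04, adjusted p = 5.8e-06, and 0.036 with an estimated correlation). The lower member was MYC, the higher ones included ZNRF3 (1.70) and LEF1 (1.66), and 7 were higher and 2 lower adjusted over the list alone. Cholesterol synthesis and SREBP targets rose, with 20 of 24 higher and none lower (median 0.77, adjusted p = 1.4e-24) and 21 higher adjusted over the list alone. INSIG1 (1.81), SCD (1.70), STARD4, a sterol carrier (1.45), and SQLE, squalene epoxidase (1.05), were examples. Integrated stress response genes rose, with 22 of 25 higher and none lower (median 0.61, adjusted p = 9.6e-24) and 23 higher adjusted over the list alone, including TRIB3 (1.74), ASNS (1.33) and VLDLR (1.04). ER chaperones rose, with 7 of 19 higher by either way of adjusting (median 0.16, adjusted p = 1.8e-04, and 0.021 with an estimated correlation), including DNAJB9 (0.70) and XBP1 (0.56).

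TGF-beta and YAP targets fell at 18 h, with 12 of 23 lower and 1 higher (median -0.44, adjusted p = 1.7e-08, and 0.0054 with an estimated correlation), and 14 lower and 1 higher adjusted over the list alone. CCN2 fell from 12272 ± 863 to 3703 ± 350 (log2 -1.73, SE 0.07), CCN1 changed by -1.61 and THBS1 by -1.07. The higher member was FN1, fibronectin (1.14). G2/M and mitosis genes fell, with 14 of 32 lower and none higher (median -0.23, adjusted p = 5.9e-08, and 0.035 with an estimated correlation) and 18 lower adjusted over the list alone. CDC25C, the phosphatase that activates CDK1 (-0.92), KIF20A (-0.64), NEK2 (-0.48) and NUSAP1 (-0.45) were lower. NF-kB targets fell, with 6 of 24 lower and none higher by either way of adjusting (median -0.17, adjusted p = 0.0035, and 0.021 with an estimated correlation). PLAU, urokinase (-1.75), the chemokine genes CCL2 (-1.68) and CXCL8 (-1.28), TNFAIP2 (-1.17) and NFKBIA, the inhibitor of NF-kB (-0.68), were lower. MYC-activated targets rose by a median of 0.08 (adjusted p = 0.017, and adjusted p = 0.128 with an estimated correlation), with 5 of 29 higher by either way of adjusting, including SHMT2 (0.62), CDK4 (0.38), NOP16 (0.45) and CAD (0.37). These 8 of 25 lists shifted at 18 h, and 7 of them did with an estimated correlation.

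CYLD, a deubiquitinase gene, was among the largest falls at 18 h (-2.00, adjusted p = 0.019), but its call was lost without DMSO replicate 3 or enzastaurin replicate 3 (adjusted p up to 0.134), and its 4 other probe sets showed -1.07 (adjusted p = 0.0155), -0.61, -0.51 and 0.10. Subtracting array medians left 1187 genes at 18 h and ended 9 calls of named genes, among them PRKCD, CAD, PGM2, UGP2 and GYG1. Averaging probe sets ended the 18 h calls of XBP1, CDC25C, NOP16, CAD, KLF4, GADD45B, FOXO3, WIPI2, ALDH1A3, NES, SOX2, EGFR and UGP2.

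**Figure D1:**
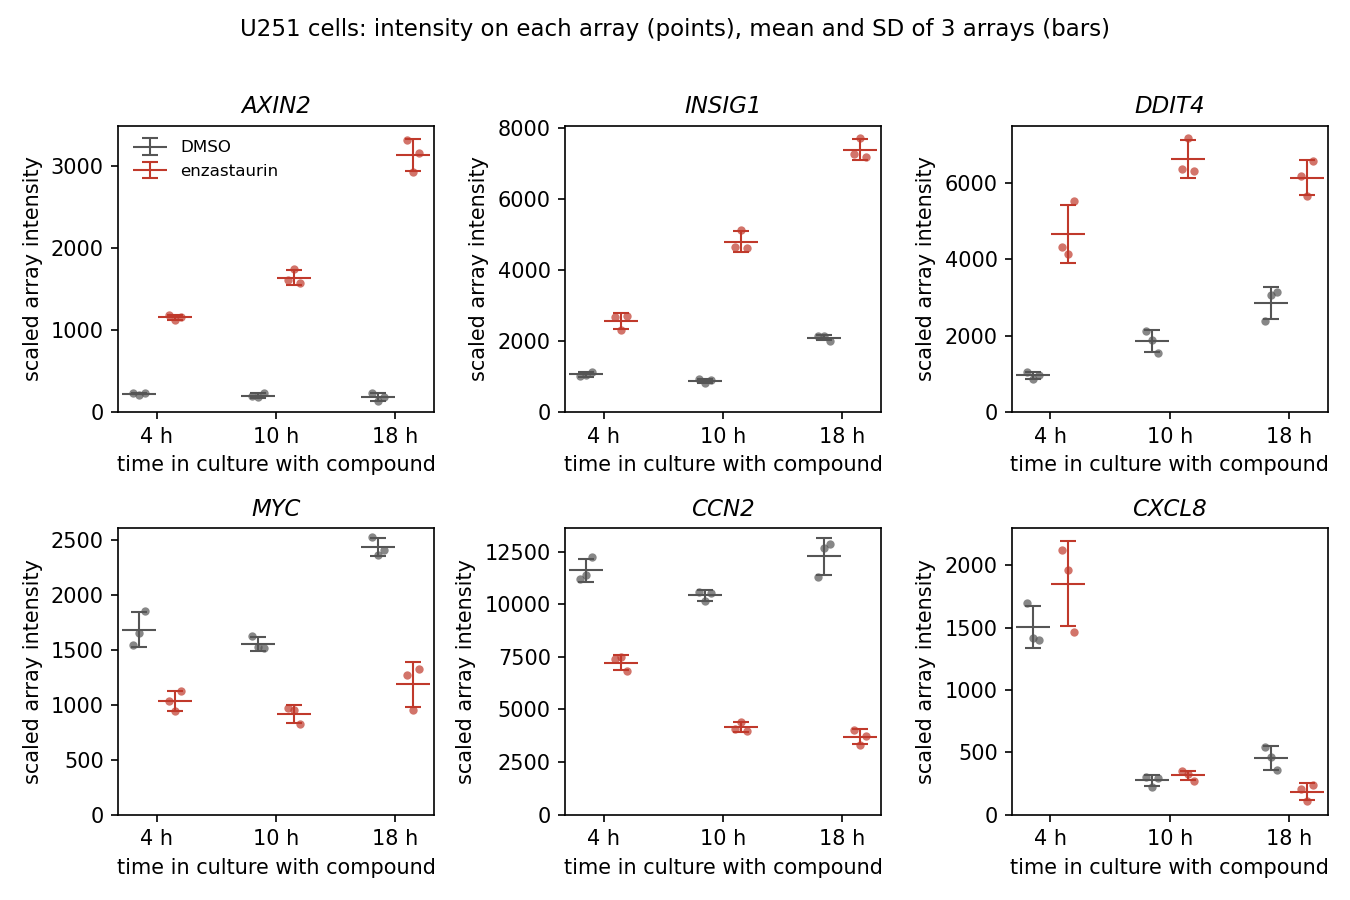
Scaled array intensity (linear axis) of 6 genes against hours of exposure in DMSO (grey) and enzastaurin (red). Points are single arrays and bars give the mean ± SD of 3 arrays per group. AXIN2 reached 3138 after 18 h of enzastaurin against 185 in DMSO, and MYC 1184 against 2433.

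The genes that act on glucose, the theme in the title, changed in both directions. In the glycolysis and glucose uptake list (21 measured), PFKFB3, which makes an activator of glycolysis, was lower at 4, 10 and 18 h (-0.57, -0.63 and -0.81). HK2, a hexokinase, was higher at 10 and 18 h (0.46 and 0.74), but averaging its probe sets turned the 10 h value to -0.14 and ended both calls. The glucose transporter gene SLC2A3 (1.66) and ENO2, an enolase (0.62), were higher at 18 h and PFKP (-0.26) was lower. Counts of members higher and lower were 0 and 1, 1 and 1, and 3 and 2 at 4, 10 and 18 h, the same adjusted over the list alone. The list did not shift (adjusted p = 0.87, 0.33 and 0.94), and at 18 h its median was -0.05 but its mean 0.08. Glycogen and gluconeogenesis genes (16 measured) did not shift either (adjusted p = 0.51, 0.54 and 0.61). PCK2, a mitochondrial gluconeogenic enzyme, was higher at 10 and 18 h (0.60 and 0.84). At 18 h PGM2 (-0.34), UGP2 (-0.21) and GYG1 (0.22) also passed, with calls lost without any 1 of 2, 2 and 4 of the 6 arrays (adjusted p up to 0.118, 0.108 and 0.126). Members higher and lower were 0 and 0, 1 and 0, and 2 and 3, against 0 and 1, 2 and 1, and 2 and 3 adjusted over the list alone.

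Of the mRNAs of the kinases themselves, few passed. None of the 9 measured drug target genes passed at 4 or 10 h, and 1 was lower at 10 h adjusted over the list alone. At 18 h GSK3B was higher (0.48, adjusted p = 6.8e-05), PRKCA lower (-0.40, adjusted p = 0.0010) and PRKCD lower (-1.23, adjusted p = 0.049), the same number adjusted over the list alone. The PRKCA call was lost when its probe sets were averaged, and the PRKCD call was lost without any 1 of 5 of the 6 arrays (adjusted p up to 0.247). The others at 18 h were GSK3A 0.08, PRKCB -0.49, PRKCE 0.33, PRKCH -0.41, PRKCQ 0.16 and PRKCI -0.09. The list did not shift (adjusted p = 0.93, 0.93 and 0.72), and at 10 h its median (0.06) and mean (0.02) lay above 0 while the test pointed downward. At 4 h the values were GSK3A -0.20, GSK3B -0.13, PRKCA -0.01, PRKCB -0.42, PRKCD -0.11, PRKCE 0.17, PRKCH 0.09, PRKCQ 0.31 and PRKCI 0.07. At 10 h they were 0.22, 0.06, -0.18, 0.23, 0.49, 0.10, -0.50, -0.02 and -0.23 in the same order.

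The lists of p53 targets and of apoptosis regulators did not shift, although single members passed. In the p53 list (18 measured), FAS (1.23 and 2.19), GDF15, a stress cytokine (1.17 and 1.41), and PMAIP1, a pro-apoptotic BCL2 family gene (0.31 and 0.67), were higher at 10 and 18 h. CDKN1A was lower at 10 h (-0.68), as was TP53INP1 (-0.88). Members higher and lower were 0 and 0, 4 and 2, and 4 and 0 at 4, 10 and 18 h, against 0 and 2, 4 and 3, and 4 and 0 adjusted over the list alone, and the list did not shift (adjusted p = 0.15, 0.25 and 0.078). In the list of apoptosis regulators (25 measured), BCL2L11, which encodes the killer protein BIM, was higher at 10 and 18 h (0.30 and 0.90). CASP6 was lower at both (-0.60 and -0.54) and CASP2 at 4 and 10 h (-0.32 and -0.30). Members higher and lower were 0 and 1, 3 and 2, and 4 and 2, against 0 and 3, 3 and 5, and 4 and 2 adjusted over the list alone. That list did not shift (adjusted p = 0.084, 0.93 and 0.51), and at 18 h its median was -0.01 but its mean 0.12. The CASP2 call at 4 h was lost without any 1 of 4 of the 6 arrays (adjusted p up to 0.116) and that of PMAIP1 at 10 h without any 1 of 2 (up to 0.0730).

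Several lists did not shift at some times. NF-kB targets had adjusted p values of 0.087 at 4 h and 0.46 at 10 h, with 1 and 2 members lower (3 and 2 adjusted over the list alone), among them IER3 (-0.41 and -0.30) and TNFAIP2 at 10 h (-0.73). Wnt targets had 0.084 at 4 h, with 3 higher and 2 lower (5 and 3 adjusted over the list alone), including TNFRSF19 (0.79), ZNRF3 (0.76) and DKK1 (-0.51). MYC-repressed targets had 0.93 at 18 h, with KLF4 (0.95) and GADD45A (0.44) higher and NDRG1 (-0.55) and GADD45B (-0.40) lower, and 2 and 3 adjusted over the list alone. G2/M and mitosis genes had 0.93 at 10 h, with 2 higher and 3 lower, among them PLK1 (0.27) and TOP2A (-0.36), and 3 and 3 adjusted over the list alone, and the mean was -0.01 while the test pointed upward. Immediate early and ERK feedback genes had 0.16 at 10 h and 0.39 at 18 h, with 2 higher and 7 lower and then 8 higher and 4 lower (6 and 10, and 8 and 4, adjusted over the list alone). ETV1 (-1.02) and DUSP6 (-0.71) were lower at 10 h, and the ERK feedback gene SPRY4 (0.93) and EGR1 (0.90) were higher at 18 h. FOXO targets had 0.93 at both later times, with 4 higher and 3 lower at 10 h and 4 and 4 at 18 h (4 and 5, and 5 and 5, adjusted over the list alone), including TXNIP (0.51 and 0.73) and FOXO3 (0.41 at 18 h). At 18 h the FOXO median (-0.01) and mean (-0.06) lay below 0 while the test pointed upward. Interferon-stimulated genes had 0.63 at 4 h, with none passing either way, and 0.17 at 18 h, with 1 higher and 6 lower by either way of adjusting, including ISG15 (-0.76) and IFIT1 (-1.73).

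Further lists did not shift at 4, 10 or 18 h. G1/S and DNA replication genes (32 measured, adjusted p = 0.53, 0.76 and 0.17) had 1 and 1, 3 and 1, and 7 and 3 members higher and lower, against 1 and 1, 4 and 3, and 9 and 3 adjusted over the list alone. CCNE2, cyclin E2 (0.52), FEN1 (0.51) and RFC5 (0.31) were higher at 18 h, and TK1 (-0.35) was lower. Hypoxia response genes (18 measured, 0.085, 0.17 and 0.93) had 2 and 2, 2 and 4, and 4 and 5, against 2 and 3, 3 and 6, and 4 and 5 adjusted over the list alone. VEGFA, the angiogenic growth factor, was higher (0.47, 1.26 and 1.21), and BNIP3L, a mitophagy receptor, was lower at 10 and 18 h (-0.69 and -1.23). Their median (0.00) and mean (0.03) at 18 h were not below 0 while the test pointed downward. Heat shock genes (15 measured, 0.94, 0.94 and 0.63) had 0 and 0, 1 and 2, and 2 and 3, against 1 and 1, 2 and 3, and 2 and 3 adjusted over the list alone, with DNAJB1 higher (0.61 and 0.58 at 10 and 18 h) and HSPB1 lower at 18 h (-0.55). Autophagy and lysosome genes (27 measured, 0.75, 0.94 and 0.51) had 0 and 0, 1 and 2, and 6 and 4, against 0 and 0, 1 and 2, and 8 and 5 adjusted over the list alone. NEU1, a lysosomal sialidase (1.23), was higher and WIPI2 (-0.68) and GABARAPL1 (-0.57) lower at 18 h. NRF2 targets (17 measured, 0.066, 0.51 and 0.94) had 0 and 0, 1 and 3, and 3 and 4, against 0 and 0, 1 and 3, and 4 and 4 adjusted over the list alone, with NQO1 (-0.54) lower and SRXN1 (0.45) higher at 18 h. Their median at 18 h was 0.02 but their mean -0.04. Aryl hydrocarbon receptor targets (8 measured, 0.067, 0.19 and 0.75) had 0 and 0, 2 and 1, and 2 and 2, against 0 and 0, 4 and 1, and 2 and 3 adjusted over the list alone, with ALDH1A3, a retinal dehydrogenase, higher at 10 h (0.54) and lower at 18 h (-0.42).

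Astroglial and glioma markers (12 measured, adjusted p = 0.94, 0.51 and 0.93) had 0 and 1, 0 and 0, and 3 and 2 members higher and lower at 4, 10 and 18 h, the same adjusted over the list alone. The stem cell factor SOX2 was lower at 4 h (-0.54) and higher at 18 h (0.45), and at 18 h NES, nestin (-0.67), and PDGFRA were lower and EGFR (0.53) was higher. The median at 18 h was 0.04 but the mean -0.13, and at 4 h 0.02 but -0.01. Of the markers of other cell types, 5 were measured (HBB, MBP, CD3E, CSF1R and PECAM1), none passed at any time by either way of adjusting, and the adjusted p values of the list were 0.93, 0.94 and 0.93.

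**Figure D2:**
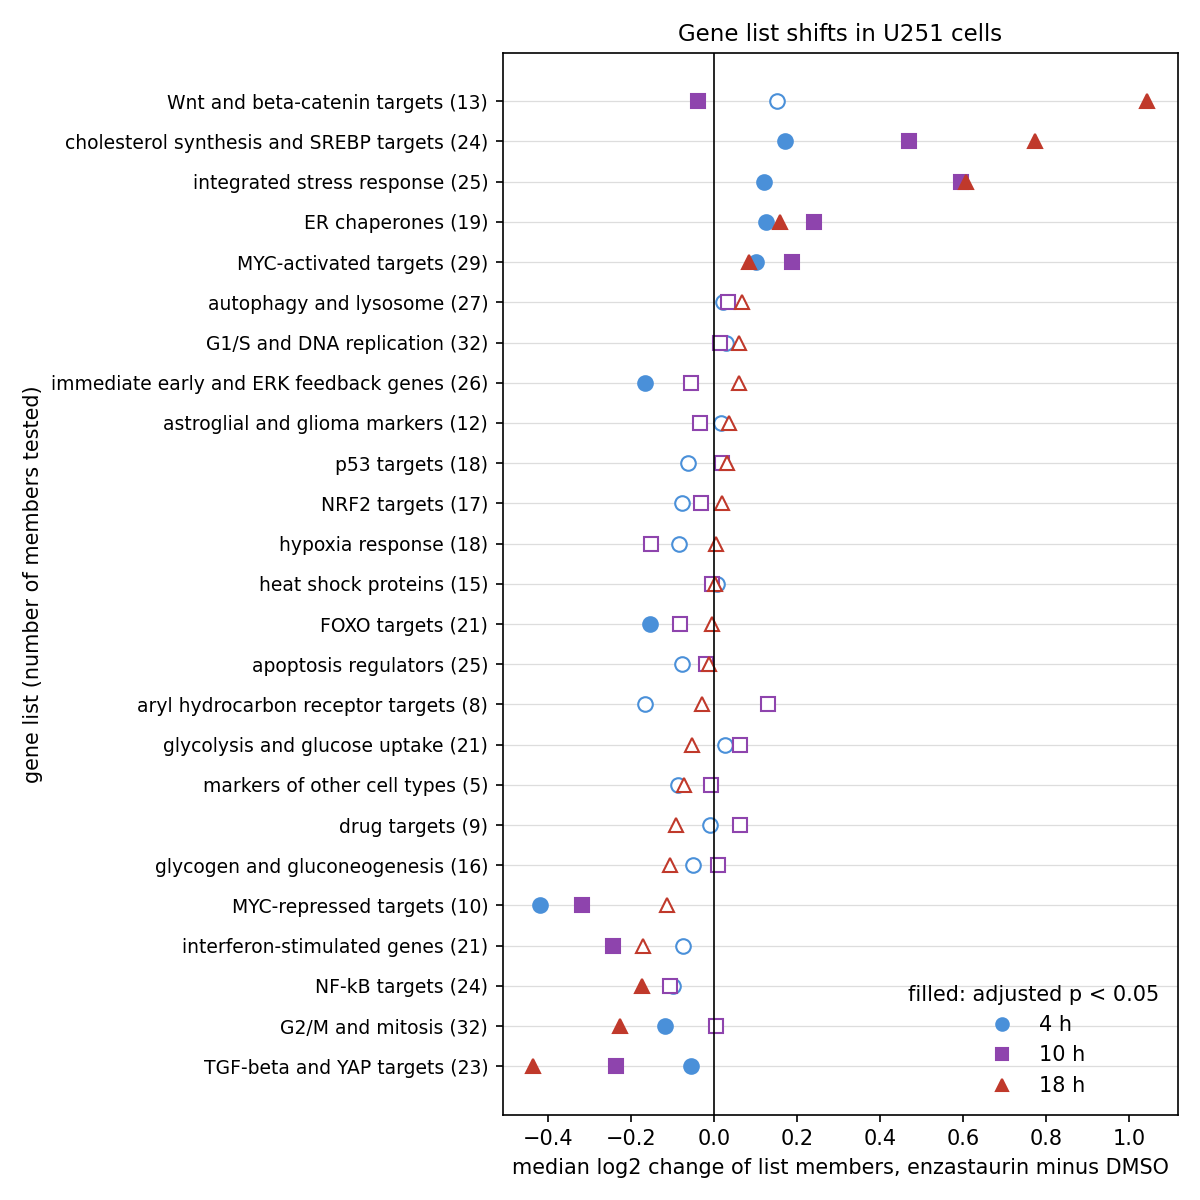
Median log2 change between enzastaurin and DMSO of each of the 25 gene lists at 4, 10 and 18 h. Filled points have an adjusted p under the threshold in the list test, and the Wnt list at 10 h was called upward although its median was -0.04. Cholesterol synthesis and SREBP targets reached 0.77 at 18 h and TGF-beta and YAP targets -0.44.

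On average over the 3 times, 2291 genes differed between enzastaurin and DMSO, 1123 higher and 1168 lower, 38 of them at least 2-fold. With array medians subtracted there were 1571, 1020 higher and 551 lower, and with quantile normalization 2365, 1126 higher and 1239 lower. The largest rises were those of AXIN2 (3.08, SE 0.08, adjusted p = 1.0e-16), INSIG1 (1.83), DDIT4 (1.73), LIPG (1.63) and TNFRSF19 (1.55). The largest falls were those of DHRS3 (-1.73), EFNA1 (-1.57), the interferon-induced gene IFIT1 (-1.33), KCTD4 (-1.31) and UBALD2 (-1.31). At each of the 3 times 29 genes were higher and 39 lower, among the lower ones MYC, CCN1 and CCN2. The 10 and 18 h comparisons share no arrays, and 281 genes were higher in both (37.8 by chance) and 321 lower in both (45.8 by chance), with 14 in opposite directions (83.8 by chance). Between 4 and 10 h the numbers were 37 (2.60), 62 (7.26) and 5 (9.07), and between 4 and 18 h 33 (5.59), 48 (12.2) and 23 (18.0). These counts run across genes, which are not independent replicates.

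On average over the times 10 of 25 lists shifted. Cholesterol synthesis and SREBP targets (median 0.45, adjusted p = 1.1e-26), integrated stress response genes (0.43, adjusted p = 5.6e-28), ER chaperones (0.15, adjusted p = 1.2e-09) and MYC-activated targets (0.10, adjusted p = 3.3e-06) rose, with 21, 21, 11 and 13 members higher and none lower. TGF-beta and YAP targets (-0.28, adjusted p = 3.9e-07) and NF-kB targets (-0.17, adjusted p = 0.0035) fell, with 14 and 6 members lower and 2 and 0 higher. The other 4 calls were lost with an estimated correlation. Wnt targets rose (median 0.26, adjusted p = 3.5e-04, and adjusted p = 0.0776 with an estimated correlation), G2/M and mitosis genes fell (-0.11, adjusted p = 3.3e-06, and adjusted p = 0.0531 with an estimated correlation), MYC-repressed targets fell (-0.21, adjusted p = 0.018, and adjusted p = 0.25 with an estimated correlation) and interferon-stimulated genes fell (-0.18, adjusted p = 0.046, and adjusted p = 0.31 with an estimated correlation).

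Some effects differed between the times when the difference itself was tested. From 4 to 10 h, the effect on LIPG grew by 2.02 (SE 0.29, adjusted p = 9.1e-04) and that on SESN2 by 1.40, while the effects on LFNG (-1.60) and PRSS35 (-1.36) moved downward. From 10 to 18 h, PLAU (-1.65, adjusted p = 4.7e-08), CXCL8 (-1.48) and THBS1 (-1.14) moved downward and NKD1 (1.74) upward. From 4 to 18 h, NKD1 (2.78), SYTL2 (2.22) and LIPG (2.09) moved upward and DHRS3 (-3.60) and PRSS35 (-2.35) downward. The numbers of genes were 174 from 4 to 10 h (100 upward, 74 downward), 276 from 10 to 18 h (164 and 112) and 963 from 4 to 18 h (504 and 459). With array medians subtracted they were 26 (8 and 18), 65 (35 and 30) and 546 (143 and 403). The balance from 4 to 10 h and from 4 to 18 h then turned downward. With quantile normalization they were 185 (112 and 73), 306 (179 and 127) and 1050 (570 and 480), and the balance stayed upward. From 4 to 10 h replicate blocks gave 66, and leaving out 1 array gave 67 to 154, a move of over 1.5 times for 10 of the 12 arrays (all but enzastaurin 4 h replicate 3 and enzastaurin 10 h replicate 3). From 10 to 18 h the number was 181 without DMSO 10 h replicate 2. The change of the MYC effect did not pass between any 2 times (-0.06, -0.29 and -0.35, adjusted p = 0.941, 0.426 and 0.190). Averaging probe sets ended the calls of LFNG from 4 to 10 h and of NKD1 from 10 to 18 h.

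From 4 to 10 h the effect on 4 lists moved upward with either correlation. These were integrated stress response genes (median difference 0.45), cholesterol synthesis and SREBP targets (0.37), ER chaperones (0.15) and p53 targets (0.14, adjusted p = 0.014, and 0.0491 with an estimated correlation). The p53 list had shifted at neither time, with a median of -0.06 at 4 h and 0.02 at 10 h. From 10 to 18 h it moved upward for Wnt targets (0.56) and downward for NF-kB targets (-0.21) and for G2/M and mitosis genes (-0.23), each with an adjusted p of 0.0499 with an estimated correlation. From 4 to 18 h it moved upward for Wnt targets (0.94), cholesterol synthesis and SREBP targets (0.59), integrated stress response genes (0.47) and p53 targets (0.24) and downward for TGF-beta and YAP targets (-0.26). With the fixed correlation 10, 8 and 6 lists passed.

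DMSO cells changed on their own between 4 and 18 h, which is the background for the enzastaurin effects. ALDH1A3 fell from 7961 ± 432 to 1463 ± 69.1 (SD, n = 3 each, log2 -2.43, SE 0.09, adjusted p = 2.2e-13). DIRAS3, a small GTPase gene (-2.33), the secretogranin gene SCG2 (-2.01), TAMALIN (-2.19) and CTNNBIP1 (-1.87) also fell. EGR1, an immediate early transcription factor, rose from 229 ± 42.8 to 1047 ± 65.9 (log2 2.13, SE 0.16), and DHRS3 (3.04), CCDC85B (2.16), BORCS5 (1.98) and JAKMIP3 (1.90) rose as well. The falls of TAMALIN at 4 h (-2.40) and of DHRS3 at 18 h (-3.54) in enzastaurin use the same DMSO arrays of those times. They are therefore not independent of the changes of these genes in DMSO cells. MYC rose by 0.53 (adjusted p = 0.0013), and AXIN2 did not pass (-0.28, adjusted p = 0.163). In total 2518 genes changed, 1404 higher and 1114 lower, 164 at least 2-fold. The CTNNBIP1 call was lost without DMSO 18 h replicate 2 (adjusted p = 0.0556), and subtracting array medians left 1536 genes.

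In DMSO cells 7 of 25 lists shifted over the same period. MYC-activated targets fell (median -0.15, adjusted p = 3.9e-05, and 0.027 with an estimated correlation), with 1 of 29 higher and 12 lower, and 13 lower adjusted over the list alone. CAD (-0.58) and CDK4 (-0.35) were lower. G1/S and DNA replication genes fell (median -0.12, adjusted p = 0.0032, and 0.027 with an estimated correlation), with 3 of 32 higher and 9 lower, including CCNE2 (-0.53), and 3 and 11 adjusted over the list alone. The other calls were lost with an estimated correlation. NRF2 targets rose (median 0.28, adjusted p = 2.6e-04, and adjusted p = 0.29 with an estimated correlation), with 9 of 17 higher and 11 adjusted over the list alone, including NQO1 (0.45). Immediate early and ERK feedback genes rose (median 0.26, adjusted p = 2.6e-04, and adjusted p = 0.13 with an estimated correlation), with 13 of 26 higher and 1 lower, 14 and 1 adjusted over the list alone, including PHLDA1 (1.41). Integrated stress response genes rose (median 0.08, adjusted p = 0.015, and adjusted p = 0.35 with an estimated correlation), with 9 higher and 2 lower, and 10 and 2 adjusted over the list alone. Autophagy and lysosome genes rose (median 0.11, adjusted p = 0.021, and adjusted p = 0.29 with an estimated correlation), with 6 higher by either way of adjusting, including GABARAPL1 (0.64). G2/M and mitosis genes fell (median -0.09, adjusted p = 0.0032, and adjusted p = 0.29 with an estimated correlation), with 2 higher and 9 lower by either way of adjusting, including AURKA (-0.55).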

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

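The test of whether scaling lowers MYC was chosen only after the result was seen, and the other tests here were written before it. The genes and lists named first passed a test of the difference between the enzastaurin effects at different times.

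The effect differed between 4 and 10 h for 174 genes, between 10 and 18 h for 276 and between 4 and 18 h for 963. Leaving out 1 array gave 67 to 154 from 4 to 10 h and 181 to 286 from 10 to 18 h, the lowest without enzastaurin 4 h replicate 1 and without DMSO 10 h replicate 2. From 4 to 10 h the largest log2 differences were TAMALIN 2.38, LIPG 2.02, ZFP36 1.90, CILP 1.52, SESN2 1.40, SALL2 -2.35, LFNG -1.60, PRSS35 -1.36, RARB -1.15 and CAPS -1.07. Leaving out 1 array ended the calls of TAMALIN (11 of 12 arrays, adjusted p up to 0.109), ZFP36 (9, up to 0.0864), CILP (11, up to 0.131) and CAPS (10, up to 0.123). From 10 to 18 h they were PCDHAC1 2.45, GPRC5B 2.11, SIMC1P1 2.09, NKD1 1.74, ZSCAN20 1.57, ASPG -2.19, ELFN2 -1.79, PLAU -1.65, CXCL8 -1.48 and THBS1 -1.14. Leaving out 1 array ended the calls of PCDHAC1 (6 of 12, up to 0.0818), GPRC5B (11, up to 0.113), ZSCAN20 (10, up to 0.108) and ASPG (8, up to 0.0905). From 4 to 18 h they were TAMALIN 3.60, NKD1 2.78, GPRC5B 2.54, SYTL2 2.22, LIPG 2.09, DHRS3 -3.60, EWSAT1 -2.95, PRSS35 -2.35, PDGFRA -2.09 and CAPS -1.94. Leaving out 1 array ended the calls of EWSAT1 (6 of 12, up to 0.0632) and PDGFRA (6, up to 0.0722).

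Lists whose median effect differed with either correlation were, from 4 to 10 h, integrated stress response 0.45, cholesterol synthesis and SREBP targets 0.37, ER chaperones 0.15 and p53 targets 0.14. From 10 to 18 h they were Wnt and beta-catenin targets 0.56, NF-kB targets -0.21 and G2/M and mitosis -0.23. From 4 to 18 h they were Wnt and beta-catenin targets 0.94, cholesterol synthesis and SREBP targets 0.59, integrated stress response 0.47, p53 targets 0.24 and TGF-beta and YAP targets -0.26.

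Other splits of the same arrays were counted. For 4, 10 and 18 h and for DMSO over time the 10 splits are too few for a share under 0.05. There 1 split, the real one, gave 224, 1046, 1981 and 2518 genes, and the highest other gave 1, 1, 0 and 2. For the average over the times a chance arrangement of these arrays is excluded, as 1 of 100 splits reached the real 2291 and the highest other gave 326. Since the replicates may be technical, this does not cover chance differences between cultures. For the list shifts a chance arrangement of these arrays is excluded with the same limit, as 1 of 100 reached the real 25 and the highest other gave 20. The median of the other splits was 8 of 75 list tests, so single list calls are weaker evidence than their number. For the difference between 4 and 10 h chance is not excluded, since 8 of 100 splits reached 174 and the highest gave 1095. Splits with counts this high point to a structure of the arrays, as the 7 others each kept the real groups of 1 time whole and so hold the enzastaurin effect, and the highest count among splits that mix both times was 0. For 10 to 18 h 4 of 100 splits reached 276 (highest other 1088), and for 4 to 18 h 2 of 100 reached 963 (highest other 1511). Both shares are under 0.05. There too the 3 and 1 others kept the real groups of at least 1 time whole, and splits mixing both times gave at most 1. The splits shuffle treatment within each time, so they ask whether enzastaurin had any effect. They cannot tell an effect that differs between times from an equal one, so they exclude chance for none of these differences.

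Across genes, the 10 h effect ran against the change of DMSO cells between 4 and 18 h. Of 529 genes called in both, 457 went in opposite directions (108 by chance) and 72 in the same (105 by chance), and the correlation was -0.249 with no shared array. It lay between -0.250 and -0.211 without any 1 of the 12 arrays, so it did not rest on a single array. The comparisons have no array in common by design, so this is no test of shared arrays. After quantile normalization it was -0.249, which argues against scaling that depends on level. A candidate explanation is that enzastaurin holds back part of the change of cells in culture, a hypothesis found in these data at 10 h. The 4 h effect against DMSO from 10 to 18 h gave -0.0612 and the 18 h effect against DMSO from 4 to 10 h gave 0.0159. These share no array either, and the pattern is not shown for them. The 18 h value lay between -0.0104 and 0.064 without any 1 array. It cannot tell whether the change from 4 to 10 h was still held back at 18 h. The 18 h effect is measured against DMSO cells at 18 h, in which that change may have reversed.

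At 18 h 551 of 807 genes called in both comparisons went in opposite directions (201 by chance) and 256 in the same (202 by chance). Both of these comparisons use the DMSO arrays at 18 h, and their noise alone, simulated with no change, gave 65.2% of the covariance across genes. The covariance was -0.0343 (-0.0488 to -0.0335 without any 1 array), further below 0 than in any of 100 simulations (-0.0247 to -0.0202). The simulations assume noise that is independent between genes, so their range sets no firm bound. The 65.2% lies between the shares set beforehand, and whether an opposing effect adds to the noise stays open.

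At 4 h 45 of 100 genes called in both comparisons went in opposite directions and 55 in the same. These comparisons share the DMSO arrays at 4 h, whose noise alone moves genes in the same direction, and its share was not simulated, so the counts are given without weighing them.

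MYC mRNA was lower while the MYC-activated targets were higher as a list at 4, 10 and 18 h, with 0, 6 and 5 of 29 members passing. The list median lay at the 99.74th percentile or above among 10000 random lists matched on mean level, which argues against bright genes being moved up by scaling. Under the other scalings MYC changed by -0.582 or further down, which argues against scaling as the source of its fall, although with array medians subtracted the 4 h call was lost. There the change was -0.58 (SE 0.141, adjusted p = 0.0582) against -0.70 (SE 0.107), a smaller change with a larger error. No biological explanation was tested, and with an estimated correlation the list passed only at 10 h (adjusted p = 0.081, 0.0084 and 0.128). MYC and this list also moved in opposite directions without enzastaurin. In DMSO cells from 4 to 18 h MYC rose while the list fell (median -0.15, adjusted p = 3.9e-05, and 0.027 with an estimated correlation). The 4 and 18 h effects share DMSO arrays with that change.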

How the results depend on the processing

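The alternative that left out together enzastaurin 10 h replicate 3 and enzastaurin 18 h replicate 3, the arrays furthest from their groups, was chosen only after the data were seen, and the other alternatives were set before the data were examined. The cause was not tested for the changes below unless the alternative itself shows it.

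With array medians subtracted the counts were 79 at 4 h (74 of them shared with the 224), 443 at 10 h, 1187 at 18 h and 1536 for DMSO over time, and 26, 65 and 546 for the differences from 4 to 10, 10 to 18 and 4 to 18 h. The share of higher genes at 4 h went from 30.8% to 68.4%, and the median change of all genes was then 0.12. Array medians at 4 h were 123.7, 118.2 and 110.8 in DMSO against 108.5, 114 and 99.5 in enzastaurin. Subtracting them therefore moved every 4 h change upward by construction. Why the array medians differed, and why the other counts fell, was not tested. With quantile normalization the 3 times gave 241, 1066 and 2129, and the share of higher genes at 4 h was 27%.

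Averaging the probe sets of a gene gave 133 at 4 h, 658 at 10 h, and 81, 131 and 577 for the differences, and the cause was not tested. It reversed HK2 at 10 h (-0.14, adjusted p = 0.82, against 0.46), ATP6V1H at 10 h (-0.028, adjusted p = 0.96, against 0.33), UGP2 at 18 h (0.23, adjusted p = 0.60, against -0.21) and TNFRSF10B at 18 h (-0.13, adjusted p = 0.66, against 0.26), and the cause was not tested. Every probe set on its own gave 3068 at 18 h, 3696 on average and 4448 for DMSO, with 27307 probe sets tested.

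Only the groups compared, with fewer arrays for the spread, gave 139 at 4 h, and for the average it is the same fit. From 4 to 10 h no trend gave 90, replicate blocks 66 and no level filter 114. From 10 to 18 h replicate blocks gave 181, and leaving out both deviating arrays 168. A 2-fold minimum, stricter by construction, gave 16, 74, 197 and 38 at 4, 10 and 18 h and on average, 25, 38 and 170 for the differences and 164 for DMSO. List shifts were 25, against 16 with an estimated correlation and 38 with fry.

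With 1 array left out, with fewer arrays by construction, counts were 138 to 177 at 4 h, 653 to 791 at 10 h, 1525 to 1824 at 18 h, 2023 to 2300 on average and 1991 to 2064 for DMSO. For the differences they were 67 to 154, 181 to 286 and 704 to 906, and for lists 24 to 27. The count moved by over 1.5 times at 4 h without DMSO replicate 1 (148), DMSO replicate 3 (143) or enzastaurin replicate 1 (138), at 10 h without DMSO replicate 2 (653) or replicate 3 (685), and from 10 to 18 h without DMSO 10 h replicate 2 (181). From 4 to 10 h it did for 10 of 12 arrays.

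Calls of named genes passed or failed as before in 378 cases with an offset of 1 (2 ended), 383 with 64 (3 ended), 378 with quantile normalization (4 ended), 373 with array weights (4 ended), 326 with array medians subtracted (60 ended) and 279 with averaged probe sets (59 ended). Calls of genes that held under every alternative applied to them numbered 15 of 50 at 4 h, 47 of 82 at 10 h and 76 of 102 at 18 h. The 2-fold minimum was not applied to single named genes. A gene that an alternative left out was not counted as lost there. The list test has no 2-fold minimum and was not run for single probe sets, and the brightest 25% by level left 69 list tests. Signal over background limits dim genes, and 12376 of 19775 genes lay above the level filter.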

Other observations

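The families below were chosen only after their values were seen, and no test of an explanation was run.

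The 4 ID genes, inhibitors of basic helix-loop-helix factors, were lower in enzastaurin at 4, 10 and 18 h. ID1 changed by -0.87, -1.15 and -1.21, ID2 by -0.85, -0.66 and -0.66, ID3 by -0.44, -0.86 and -0.84, and ID4 by -0.77, -0.93 and -0.41. With array medians subtracted 2, 4 and 3 of them passed, and with quantile normalization 4 each time.

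Of 6 metallothionein genes measured (MT1E, MT1F, MT1G, MT1H, MT1X and MT2A), 0 passed at 4 h and 6 were lower at 10 and 18 h (medians -0.70 and -0.88). In DMSO cells 6 were higher at 18 h than at 4 h (median 0.75). The fall at 18 h uses the same DMSO arrays at 18 h, so it is not independent of that rise. The same numbers passed under both other scalings, and probe sets of such similar genes share signal in part.

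The Wnt receptor gene FZD2 changed by -0.90, -1.16 and -1.44 at 4, 10 and 18 h. Of 7 FZD genes measured, 3, 1 and 1 were lower, and 2 were higher at 18 h. With quantile normalization 3, 2 and 1 were lower and 2 higher at 18 h. With array medians subtracted 2, 1 and 1 were lower and 1 higher at 18 h. Of 25 collagen genes, 13 were lower and 0 higher in DMSO cells at 18 h against 4 h (median -0.51), with 15 lower after quantile normalization and 12 with array medians subtracted.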
